A study of Schizosaccharomyces pombe with 13 samples.

How the data were processed

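The measurements were small RNAs bound to Ago1, the Argonaute protein of the fission yeast Schizosaccharomyces pombe, sequenced from 13 libraries of 7 genotypes. Per the labels, the RNA was purified with Ago1 and by gel from cells grown in rich medium, ligated to adaptors at both ends and amplified by PCR. There was 1 library each for wild type, tri1Δ and rrp6Δdcr1Δ, 2 each for dcr1Δtri1Δ and rrp6Δ, and 3 each for dcr1Δ and rrp6Δtri1Δ. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

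The authors deposited coverage signal per base, as 3 tracks per genotype (both strands, plus and minus), 21 tracks in all. Reads were aligned with Novoalign version 2, per the submitters' processing notes, to a genome build that the labels name by strain and date. The handling of mismatches, of reads that match several places and of identical reads is not given in the sources used here, and it sets the level at the ribosomal DNA (rDNA), the centromeres, the subtelomeres and other repeats. Coverage adds 1 unit per base and read, so a longer RNA adds more signal than a shorter one. Tracks of genotypes with several libraries held 1 value for all of them and are the authors' mean, with no column per library.

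The values of each track were built from whole multiples, or sums of whole multiples, of a few fixed step sizes, each the worth of 1 read. In the tracks that were split this held within a relative tolerance of 1.5e-14, except for 0.0255% of unique values in rrp6Δtri1Δ. In dcr1Δ it was checked only for common low values. Wild type, tri1Δ and rrp6Δdcr1Δ had 1 step, dcr1Δtri1Δ and rrp6Δ 2, rrp6Δtri1Δ 3 and dcr1Δ 4, against 3 libraries in the dcr1Δ labels. Where the number of steps equalled the number of labelled libraries, each value was split into whole reads per library, called recovered libraries here; dcr1Δ was not split. Outside the rDNA arrays all signal could be split except 0.00915% in rrp6Δtri1Δ. In simulated tracks of 2 and 3 libraries, 100% of positions were recovered and 0% wrongly. Recovered libraries carry no replicate number from the labels. Across 2557 genes their signal correlated with r = 0.965 between the 2 rrp6Δ libraries, 0.840 to 0.942 between the rrp6Δtri1Δ libraries and 0.570 between the 2 dcr1Δtri1Δ libraries. Between genotypes it reached 0.955 for wild type and tri1Δ, 0.935 for the third rrp6Δtri1Δ library and rrp6Δ and 0.553 for the first dcr1Δtri1Δ library and tri1Δ, so libraries did not group by genotype throughout; genes are not independent replicates. No pair of recovered libraries was identical.

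Coordinates are those of the deposited tracks, and annotation and sequence came from assembly ASM294v3. The match of builds was checked with isolated blocks of signal, which should often begin with U. At the annotated 5′ base, 75.6% to 76.7% of blocks per chromosome had U, against 27.3% to 32.6% at positions 1 to 3 bases away. In each of 27 windows of 500 kb the 5′ base had the highest U share, 75.0% in the lowest window.

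Each strand position was put in 1 class, in the order rRNA, tRNA, snRNA and snoRNA genes, centromere, silent mating-type interval, subtelomere, Tf2 elements, other noncoding RNA, protein-coding sense, protein-coding antisense and intergenic. The centromere was the longest stretch without a protein-coding gene on each chromosome, the subtelomere the outer 50 kb of chromosomes I and II. The mitochondrial genome was not analysed here. Signal was scaled as a share of all nuclear signal of the 2 strand tracks, in ppm. After the data were examined, a second scaling was added: the share of signal outside the rDNA arrays, the outer 23.33 kb and 12.09 kb of chromosome III, which lie in the class intergenic apart from annotated rRNA genes.

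Genes were compared by sense signal in ppm (10000 ppm are 1% of nuclear signal) plus a pseudocount of 1 ppm, on the log2 scale, which understates the change of low genes. From 5075 usable protein-coding genes, those above the median of mean signal entered each comparison. Because the median gene differed between genotypes, gene changes are relative to the median gene, a choice made after the data were examined. Named genes followed a rule fixed before the data were examined: the 10 highest and 10 lowest genes per comparison, and always dcr1, tri1, rrp6 and ago1, with only genes past an adjusted p of 0.05 where a test was possible. Members of gene lists, rmr1 and red1 are named beyond that rule, chosen after their values were seen. The 10 gene lists were fixed likewise: RNAi and heterochromatin factors, meiotic transcripts removed by Mmi1, cytosolic ribosomal proteins, glycolysis and translation elongation, heat shock and chaperones, histones, iron and phosphate uptake, subtelomeric genes, exosome and TRAMP, and Tf2 retrotransposons. List members count as higher or lower from a log2 difference of 1 relative to the median gene, and the list median was set against 10000 random lists matched on mean signal. Of the Tf2 list 0 genes were measured as genes, so Tf2 is given as a region class. In simulated data for rrp6Δtri1Δ against rrp6Δ, 98.3% of changed genes were found and 0% of unchanged genes were called. All simulated changes were larger than 1, and only counting noise was added, without spread between libraries. The simulation therefore checks the calculation and gives no error rate for the real tracks.

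An isolated block was a run of signal of 1 height with no signal on either side, 15 to 40 nt long, taken as 1 read position; in 9000 simulated reads the share at 22 and 23 nt came out at 59.7% against a true share of 59.7%. Shares have 95% exact (Clopper-Pearson) binomial intervals. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Single tracks and authors' means have no replicate check.

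Planned tests assumed that replicated tracks held no separate libraries. Because libraries could be recovered, limma was run on log2 signal of the 3 rrp6Δtri1Δ and 2 rrp6Δ recovered libraries, each centred on its median gene, with Benjamini-Hochberg adjustment over 2522 genes. This test was added after the data were examined. For the lists it was also adjusted over the list alone. In simulated data of this size it found 100% of changes of 2 on the log2 scale and 46% of changes of 1, and called 0.560% of unchanged genes. The other comparisons have no test.

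The alternatives were other scalings, pseudocounts of 0.1 and 10 ppm, no filter or an upper-quarter filter, the combined track, heights capped at a high percentile of each track, and other definitions of blocks, centromere and subtelomere. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.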

Results

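Small RNAs bound to Ago1 were profiled in wild type and in 6 mutants of S. pombe. Dcr1 is Dicer, which cuts double-stranded RNA into small interfering RNAs. Tri1 is the nuclease called Trimmer in the series title, and Rrp6 is a nuclease of the nuclear exosome, which degrades RNA. The series asks which Ago1-bound RNAs arise without Dicer and what Trimmer does to them. Placed reads were estimated as signal divided by the step size and the mean block length. They came to about 27.5 M in wild type, 25.5 M in tri1Δ and 2.71 M in rrp6Δdcr1Δ. So 1 ppm of all nuclear signal (10000 ppm are 1%) stood for 27.5, 25.5 and 2.71 placed reads. A read placed at several copies of a repeat may count more than once, so the numbers of sequenced reads are not known. In the recovered libraries, the signal outside the rDNA arrays came to 11.2 and 1.57 M read bases in dcr1Δtri1Δ, 149 and 102 M in rrp6Δ, and 169, 123 and 90.3 M in rrp6Δtri1Δ. For dcr1Δ the depth per library is unknown.

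The deleted genes were examined first, over their coding regions. Of that of dcr1, at 1506166 to 1510290 on chromosome III, 1.45% was covered in dcr1Δ, 1.38% in dcr1Δtri1Δ and 1.33% in rrp6Δdcr1Δ. The share was 4.53% in wild type, 2.52% in tri1Δ, 65.5% in rrp6Δ and 91.7% in rrp6Δtri1Δ, so only the rrp6Δ background gave a clear difference. Of tri1, at 2555664 to 2556947 on chromosome II, 10.7% was covered in tri1Δ, 7.40% in dcr1Δtri1Δ and 29.1% in rrp6Δtri1Δ, against 18.8% in wild type, 40.3% in dcr1Δ, 97.2% in rrp6Δ and 82.0% in rrp6Δdcr1Δ. The level of rrp6Δtri1Δ over the whole coding region was 42.2 ppm against 33.1 in rrp6Δ, but 3.49 against 22.7 ppm from 2556032 to 2556899, the longest empty stretch of dcr1Δtri1Δ. In that stretch tri1Δ had 1.40 ppm and wild type 1.85 (3.34% and 14.1% covered), so tri1Δ was hardly lower in level. The rrp6 coding region, 610886 to 613277 on chromosome I, was empty in rrp6Δdcr1Δ, but held 5.17 ppm in rrp6Δ and 6.73 in rrp6Δtri1Δ against 0.246 in wild type. It was 11.01% covered in rrp6Δ and 11.95% in rrp6Δtri1Δ, less than dcr1 in the same tracks, and 6.73% in wild type. It was empty from 612129 to its end in rrp6Δ and from 611823 in rrp6Δtri1Δ, and also from 612234 in dcr1Δtri1Δ, which has the gene but only 0.293 ppm over it.

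Without Dicer, the small RNAs of centromeres, subtelomeres and ura4 were far lower. In dcr1Δ, centromeres held 0.301% of all signal against 80.3% in wild type (log2 ratio -8.06), and subtelomeres 0.00368% against 0.872% (-7.89). ura4, a gene of uracil synthesis at 115589 to 116625 on chromosome III, had 1.30 ppm in dcr1Δ and 2431 in wild type, -11.03 relative to the median gene. The subtelomeric helicase genes tlh1 and tlh2 were at -9.71 and -9.46, and their neighbour SPAC212.06C at -5.48; 92.3% to 99.6% of each of these 3 consists of sequence found elsewhere. The rDNA arrays took 94.0% of signal in dcr1Δ and 16.8% in wild type. Outside them centromeres held 5.04% and 96.6% (-4.26) and subtelomeres 0.0615% and 1.05% (-4.09), while tRNA genes held 23.5% and 0.993%.

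Many of the genes with the largest changes in dcr1Δ had nearly all signal at 1 site. Such single-site genes were a minority of all genes at least 1 from the median gene. They made up 26 of 192 higher genes (13.5%) and 8 of 51 lower genes (15.7%). SPBC530.02 (6114 ppm in dcr1Δ, 122 in wild type, 4.65 relative to the median gene, but -1.44 with heights capped) had nearly all of it on 23 nt of a coding exon, TATTGACGCTACCCGTAAAATGG, at 787800 to 787822 on the plus strand of chromosome II. In the membrane transporter gene mfs2 (4.72) the site was the 22 nt TATTGATACTACTGCTGATGAT in a coding exon, at 114205 to 114226 on the plus strand of chromosome I. SPCC330.03C (4.23), the meiotic cohesin gene rec8 (4.003) and the ATP synthase gene atp2 (3.42) were of the same kind, as were SPAC2G11.09, sum2 and pmp3 at 3.14 to 3.41. pyp3, a tyrosine phosphatase gene, stood highest at 9.11, and top2, the topoisomerase II gene, at 3.32; their sites shared 12 and 15 of the first 17 bases with the abundant rDNA species described with the lengths. Lowest after ura4 and the 3 subtelomeric genes were rsa4 (-5.05), the transcription factor gene sep1 (-3.31), mug27 (-3.20), imt1 (-2.84), prh1 (-2.58) and med20 (-2.32). The sites of rsa4, sep1, mug27 and prh1 held runs of 14, 10, 11 and 8 bases of the 5′ adaptor given in the labels. Among the genes named in every comparison, dcr1 was at 0.75, tri1 at 1.60, rrp6 at -0.39 and ago1 at 0.28.

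Of 2534 genes, 192 were at least 1 above the median gene in dcr1Δ and 51 at least 1 below it, and the median gene itself stood 0.99 above wild type (4.43 outside the rDNA arrays). Of the 62 subtelomeric genes on the list only 4 passed the filter on mean signal, and they passed it mainly through wild type, which favours a fall. All 4 were lower, with a list median of -7.47 at the 0.01 percentile of random lists. Of 135 ribosomal protein genes 6 were higher and 13 lower (median -0.42, below all random lists), with rpl3601 at -1.20 and rpl22 at 2.32. Of 14 RNAi and heterochromatin genes 4 were higher and 0 lower (0.31, percentile 99.4), among them rdp1, the RNA-dependent RNA polymerase gene, at 1.70 and mit1 at 1.43. Of 8 iron and phosphate genes 3 were higher (0.59, percentile 98.9), including the acid phosphatase gene pho1 at 1.81. Lower medians were those of 8 meiotic genes (1 higher, -0.40, percentile 0.780), 9 histone genes (-0.23, percentile 1.42) and 19 glycolysis and elongation genes (1 higher, -0.06, percentile 1.88). For 11 heat shock genes (4 higher, hsp16 at 2.15) and 9 exosome genes the percentiles were 51.1 and 89.2. Without centring on the median gene the counts were 1249 higher and 12 lower, with a size factor 68 and 76, and on the deposited scale 14 and 183. The dcr1Δ values are authors' means over libraries of unequal weight.

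**Figure D1:**
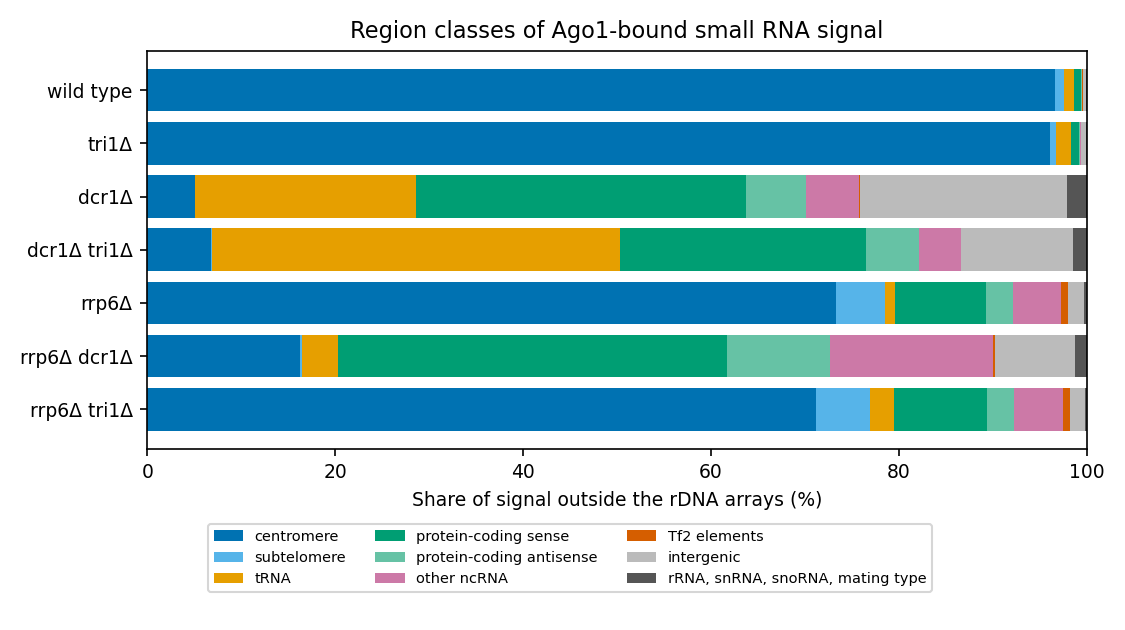
Share of the signal outside the rDNA arrays in each region class (percent, horizontal axis), with 1 bar per genotype; replicated genotypes are the authors' means, so there are no error bars. Centromeres took 96.6% in wild type and 96.1% in tri1Δ, 5.04% in dcr1Δ and 6.76% in dcr1Δtri1Δ, and 73.3% in rrp6Δ.

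In tri1Δ, as in wild type, centromeres held most of the signal. Their share was 79.5% in tri1Δ and 80.3% in wild type (log2 ratio -0.02, or -0.97 in values as deposited). tRNA genes held 1.29% and 0.826% (0.65), subtelomeres 0.545% and 0.872% (-0.68), and protein-coding sense positions 0.735% and 0.622% (0.24). The 2 lowest genes were among the single sites high in dcr1Δ: SPBC530.02 had 10.8 ppm in tri1Δ and 122 in wild type (-3.45 relative to the median gene), and mfs2 0.758 and 9.43 (-2.63). Then came the Mediator subunit gene med20 (-1.85), imt1 (-1.83), SPCC330.03C (-1.70), the subtelomeric repeat gene SPAC750.08C (-1.42), the malate transporter gene mae1 (-1.33), obr1 (-1.11), shg1 (-1.06) and cfh4 (-1.05), whose main site held 10 bases in a row of the 5′ adaptor. sum2 (1.13) and gas2 (1.04), a cell wall glucanosyltransferase gene, were the 2 genes above 1, followed by rpl22 (0.92) and 7 genes between 0.64 and 0.71. The span of gas2 overlaps that of the deleted tri1 on the other strand. Whether the altered locus itself changed the signal of gas2 was not tested.

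In tri1Δ 2 genes were at least 1 above and 11 at least 1 below the median gene, 7 of them single-site genes, of 2534, and the median gene was at 0.07. On the deposited scale the counts were 0 and 15. They depended strongly on the pseudocount, at 68 and 95 with 0.1 ppm and 0 and 1 with 10 ppm. The 7 subtelomeric genes had a median of -0.45 at the 0.02 percentile of random lists, with 1 of them lower, and tlh1 was at -0.64 and tlh2 at -0.22. In the other 8 measured lists 0 genes passed 1 in either direction and the percentiles ran from 17.4 to 86.0. dcr1 was at -0.26, tri1 at 0.34, rrp6 at 0.05 and ago1 at 0.07. With 1 library on each side, a log2 difference of this size has no replicate check.

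Of the 26 single-site genes higher in dcr1Δ than in wild type, 12 were at least 1 lower in dcr1Δtri1Δ than in dcr1Δ (median -0.61) and 1, sum2, was higher (1.25). These genes were chosen on the dcr1Δ track, which favours a fall in any other track, and in rrp6Δdcr1Δ, which has Tri1, all 26 were lower than in dcr1Δ (median -4.08). This count was added after the values were seen. Between rrp6Δtri1Δ and rrp6Δ, tracks not used for the choice, 5 of the 26 were lower and 0 higher (median -0.0258). Of the lowest genes in dcr1Δtri1Δ, SPBC530.02 had 31.7 ppm in dcr1Δtri1Δ and 6114 in dcr1Δ (-6.96 relative to the median gene, but -0.27 with heights capped), mfs2 2.94 and 543 (-6.52), SPCC330.03C 7.03 and 233 (-4.28), and rec8 1.10 and 40.8 (-3.73). atp2 (-2.68), pho1 (-2.47), SPAC2G11.09 (-2.47), sec67 (-2.15) and cys11 (-2.09) were also low, as was alp41 (-2.24), whose site shared 13 of 17 bases with the rDNA species. Centromeres held 0.194% of all signal against 0.301% (-0.64), but 6.76% against 5.04% outside the rDNA arrays (0.42), so the direction depended on the scaling. tRNA genes held 43.4% outside the arrays against 23.5%. Tf2 retrotransposons were lower on both scales (-2.20 and -1.14), as were protein-coding sense positions (-1.49 and -0.42).

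The genes highest in dcr1Δtri1Δ were mfs3 (4.16), the nuclease-helicase gene dna2 (3.81), rbm8 (3.36), SPAC26F1.08C (3.29), hac1 (3.04) and sof1 (2.81). The sites of these 6 shared 12 to 14 of the first 17 bases with the rDNA species; that of sof1, TGTTGTTGGTATTCAAAAAT, lay in a coding exon at 1988988 to 1989007 on the minus strand of chromosome II. They were followed by tri1 (2.33, with 0.613 of its 43.5 ppm in the coding region), xks1 (2.27), rpl2302 (2.20) and pmo25 (2.09), whose sites other than that of tri1 shared 11 or 12. Of 2534 genes 53 were at least 1 above and 60 at least 1 below the median gene. Ribosomal protein genes, 1 of 134 higher and 1 lower, had a median of -0.09 at percentile 99.1, and 8 iron and phosphate genes (2 lower) one of -0.45 at percentile 2.54. The other lists with enough members lay between percentiles 11.4 and 91.1, and only 2 subtelomeric genes were measured. dcr1 was at -0.71, rrp6 at -0.08 and ago1 at -0.30. Without the genes resembling the rDNA species 44 of the 53 were left. Without centring the counts were 19 higher and 436 lower, and on the deposited scale 13 and 203; the 2 dcr1Δtri1Δ libraries correlated at only 0.570.

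In rrp6Δ, Ago1-bound RNA from transposons, subtelomeres, noncoding RNAs and both strands of genes took a larger share. Tf2 retrotransposons held 0.530% of signal against 0.000210% in wild type (log2 ratio 11.30), other noncoding RNA 4.17% against 0.0734% (5.83), protein-coding antisense 2.26% against 0.0842% (4.75), protein-coding sense 7.82% against 0.622% (3.65) and subtelomeres 4.21% against 0.872% (2.27). Centromeres held 59.1% against 80.3% (-0.44, but -5.51 with a size factor over protein-coding genes). In the 2 recovered rrp6Δ libraries Tf2 held 0.519% and 0.782% of signal outside the rDNA arrays and centromeres 77.9% and 69.3%, so the centromere share in 1 wild-type library, 96.6%, lay outside the range of both.

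The median gene stood 3.06 above wild type in rrp6Δ. Relative to it the highest genes were SPAC4A8.06C (7.45; 2225 ppm in rrp6Δ, 0.528 in wild type) and its neighbour myp2 (5.27), a myosin heavy chain gene, and prm1 (6.77), lys1 (5.45) and rad50 (6.11), which flank the centromere of chromosome I. prm1 ends 8.15 kb before the centromere interval and overlaps lys1, a lysine synthesis gene, on the other strand, while the DNA repair gene rad50 starts 0.830 kb after it. SPBC18E5.10 (5.35), uvi31 (5.14), the FACT subunit gene spt16 (4.90) and the overlapping checkpoint genes swi1 (4.80) and rad3 (4.74) completed the 10, and signal covered 87.7% to 100% of each span. Lowest were rsa4 (-5.75), sep1 (-5.49) and mug27 (-3.89), with the adaptor-like sites named before, then the ribosomal protein genes rpl1902 (-4.07), rpl3401 (-4.01), rps401 (-3.94), rps1501, rps2502 and rps602 (each -3.87) and the elongation factor gene tef3 (-3.89).

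Abundant messenger RNAs stood low in rrp6Δ as whole groups. Of 123 ribosomal protein genes 108 were lower and 3 higher (median -2.77), of 19 glycolysis and elongation genes 19 lower (-2.91), both below all random lists; eno101, an enolase gene, was at -3.58. Of 7 heat shock genes 4 were lower and 1 higher (-1.62, percentile 0.0600; hsp90 at -2.73), of 6 histone genes 5 lower (-1.61, percentile 0.830; hhf1 at -2.87). Meiotic genes leaned the other way, 6 of 14 higher and 2 lower (0.51, percentile 99.5), with mug45 at 3.00, meu1 at 2.12, rec8 at 1.54 and mei4, a meiotic transcription factor gene, at 1.06, against mcp7 at -1.99. Of 29 subtelomeric genes 9 were higher and 1 lower (0.36, percentile 94.8), with ftm5 at 3.23 and tlh1 at -1.15. Of 19 RNAi and heterochromatin genes 7 were higher (0.73, percentile 88.3), led by rdp1 at 4.36 and ago1 at 2.22, with clr4, the histone methyltransferase gene, at 1.53, tri1 at 1.52 and dcr1 at 0.79. Iron and phosphate genes (3 of 8 higher) and exosome genes (2 of 9 higher, 1 lower) lay at percentiles 14.4 and 83.3, with mmi1, the meiotic RNA elimination gene, at 3.17 and rrp6 at -0.96. In all, 588 of 2522 genes were at least 1 above the median gene and 440 at least 1 below. Not relative to the median gene the counts were 2327 and 3, and with a size factor 220 and 314. When not set relative to the median gene, 36 of the ribosomal protein genes were higher and 1 lower. Of the glycolysis and elongation genes 1 was higher and 0 lower on that scale, with rpl1902 at -1.004 and tef3 at -0.83.

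With Rrp6 absent, loss of Dicer again went with low centromeric, subtelomeric and ura4 RNA, while gene-derived RNA took a larger share. Centromeres held 6.42% of signal in rrp6Δdcr1Δ and 59.1% in rrp6Δ (log2 ratio -3.20), subtelomeres 0.0864% and 4.21% (-5.61), and Tf2 retrotransposons 0.0587% and 0.530% (-3.17). Protein-coding sense held 16.3% against 7.82% (1.06), antisense 4.34% against 2.26% (0.94) and other noncoding RNA 6.87% against 4.17% (0.72). The rDNA arrays took 60.5% against 19.5%, and outside them the ratios were -2.17 for centromeres, -4.58 for subtelomeres, -2.15 for Tf2 and 2.09 for protein-coding sense. The lowest genes were ura4 (3.46 ppm against 4876, -11.57 relative to the median gene), tlh1 (-9.41), tlh2 (-9.36), SPAC212.06C (-9.29), ftm4 (-6.74), SPAC750.01 (-6.72), SPAC977.14C (-6.56), ftm5 (-6.53), ftm1 (-6.17) and SPBPB2B2.19C (-6.05). The highest were the sporulation gene spo20 (4.13), mainly through a coding exon site at 609712 to 609733 on chromosome I, hpm1 (3.12), pfl3 (3.10), svf1 (2.97), urh1 (2.93), rlp1 (2.85), pex7 (2.84), SPCC777.02 (2.80), SPCC330.07C (2.76) and gta3 (2.73). Of these, spo20 ends at 610703, just before the deleted rrp6, which starts at 610848. Likewise svf1 starts at 1511044 on chromosome III, just past the deleted dcr1, which ends at 1510557. Whether the altered loci themselves changed the signal of these neighbours was not tested.

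Of 2523 genes 260 were at least 1 above and 329 at least 1 below the median gene in rrp6Δdcr1Δ, and the median gene was 1.47 above that of rrp6Δ. Of 14 subtelomeric genes 12 were lower and 1 higher (median -6.11), and of 19 glycolysis and elongation genes 13 were lower (-1.39), both below all random lists. The 14 were those of 62 listed subtelomeric genes that passed the filter on mean signal. That filter lets in genes high in rrp6Δ alone, which favours a fall. Histone genes, 0 of 4 higher or lower, had a median of -0.87 at percentile 3.01. Iron and phosphate genes (1 of 8 higher, 2 lower), heat shock (2 of 6 lower), meiotic (1 of 14 higher, 4 lower), ribosomal (3 of 62 higher, 10 lower), exosome (1 of 11 higher, 1 lower) and RNAi genes (1 of 21 higher, 4 lower) lay between percentiles 6.09 and 41.0. arb1, a partner of Ago1, was at 1.80, clr4 at -1.94, dcr1 at -2.14, tri1 at -0.04, ago1 at -0.32 and rrp6 at -3.83. Not relative to the median gene the counts were 1838 and 72. There was 1 library, of about 2.71 M placed reads, for rrp6Δdcr1Δ.

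Between rrp6Δtri1Δ and rrp6Δ 15 of 2522 genes changed by limma on recovered libraries (Benjamini-Hochberg adjusted p under 0.05), 7 up and 8 down, with 3 against 2 libraries. Without centring on the median gene it gave 8 up and 3 down. Across genes the third rrp6Δtri1Δ library correlated more with the rrp6Δ libraries (0.935 and 0.926) than with the second of its own genotype (0.840). SPBC530.02 fell most (log2 -4.60, SE 0.27, adjusted p = 0.000295), then mfs2 (-4.20, SE 0.30, adjusted p = 0.000423), the 2 single sites that were also low without Tri1 in the other backgrounds. A further 5 of the genes that fell lay between 2092851 and 2122816 on chromosome II: the DNA glycosylase gene mag2 (-3.49), the proteasome ATPase gene rpt6 (-3.01), nvj2 (-2.82), the translation initiation factor gene sui1 (-2.36) and SPBC18E5.10 (-2.18). The last was rps2202 (-1.83). The 7 that rose were in 2 places, chosen for mention after their values were seen: gas2 (4.34, SE 0.32, adjusted p = 0.000423), dbl8 (4.18) and tri1 itself (3.18, with 42.2 of its 506 ppm in the coding region) at 2553939 to 2563169 on chromosome II, and ste6 (4.56), glm2 (3.78), ptl1 (3.65) and mme1 (3.38) at 1763151 to 1773479 on chromosome III. rmr1, beside mme1, was higher by 4.33 and red1, a gene of meiotic RNA elimination, by 5.26, but neither passed (adjusted p = 0.0586 and 0.110). Leaving out 1 recovered library moved the count from 15 to 4 when the first or the second rrp6Δ library was left out, with 0 and 1 of the 4 up, and to 58 and 37 when the second or the third rrp6Δtri1Δ library was left out.

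In rrp6Δtri1Δ tRNA genes held 2.34% of signal against 0.852% in rrp6Δ (log2 ratio 1.46), but outside the rDNA arrays 5.40%, 1.62% and 0.977% in the recovered libraries against 0.863% and 1.23%, which overlap. rRNA genes held 3.97% against 1.93% and intergenic positions 8.80% against 19.0%, while the rDNA arrays, whose signal lies in these 2 classes, held 11.4% against 19.5%. Centromeres held 63.1% of signal in rrp6Δtri1Δ and 59.1% in rrp6Δ (0.10; -0.04 outside the rDNA arrays), subtelomeres 5.04% and 4.21% (0.26) and Tf2 0.708% and 0.530% (0.42). Among recovered rrp6Δtri1Δ libraries the centromere share outside the rDNA arrays was 60.5%, 82.9% and 69.03% and that of Tf2 0.742%, 0.296% and 1.42%, ranges that enclosed the 2 rrp6Δ libraries. On the authors' means, 89 of 2522 genes were at least 1 above and 43 at least 1 below the median gene. By that measure 11 of 19 glycolysis and elongation genes were higher (median 1.03; tef3 at 1.502) and 11 of 98 ribosomal protein genes higher and 2 lower (0.48), both above all random lists, and 2 of 7 heat shock genes higher (0.41, percentile 99.1). Of 27 subtelomeric genes 1 was higher and 3 lower (-0.67, below all random lists). Percentiles of RNAi (1 of 18 higher), meiotic (1 of 14 higher, 2 lower), histone (1 of 6 higher), iron and phosphate (0 of 8) and exosome genes (1 of 10 higher) ran from 7.64 to 89.4. In the limma test 16 of the 19 glycolysis and elongation genes passed when adjusted over the list alone (adjusted p from 0.0203) and 0 over all genes tested. Of 97 ribosomal protein genes 5 passed adjusted over the list alone and 1 over all genes. That 1 gene, rps2202, fell (-1.83), against the rise of the list median. The genes red1, tri1 and hhf1, a histone H4 gene, passed adjusted over their lists alone. Of the heat shock, iron and phosphate, meiotic and subtelomeric genes 0 passed limma either way, with 1, 3, 3 and 2 at an unadjusted p under 0.05. ago1 was higher by 0.04 and dcr1 by 0.32 in the test without passing it, and rrp6 was at -0.02 on the means.

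Fewer isolated blocks were 22 or 23 nt long, and more 24 to 27 nt, in each strain without Tri1. Of isolated blocks, 37.4% (95% exact interval 37.0 to 37.9) were 22 or 23 nt long in wild type and 23.6% (23.2 to 23.9) in tri1Δ. The share was 51.3% (50.99 to 51.7) in dcr1Δ and 25.5% (25.1 to 25.9) in dcr1Δtri1Δ, and 63.0% (62.7 to 63.3) in rrp6Δ and 27.9% (27.6 to 28.1) in rrp6Δtri1Δ. rrp6Δdcr1Δ had 57.3% (56.9 to 57.6). Blocks of 24 to 27 nt made up 22.1% in wild type and 37.4% in tri1Δ, 16.4% and 31.9% in dcr1Δ and dcr1Δtri1Δ, and 15.8% and 41.6% in rrp6Δ and rrp6Δtri1Δ. Shorter blocks, of 18 to 20 nt, were also more frequent in 2 of the 3 pairs, 24.8% in dcr1Δtri1Δ against 18.2% in dcr1Δ and 16.9% in rrp6Δtri1Δ against 10.2% in rrp6Δ, but 12.1% in tri1Δ against 13.1% in wild type. There were 42738 to 103817 blocks per genotype. By recovered library, the 22 and 23 nt share of blocks of 1 read was 62.9% and 62.1% in rrp6Δ and 26.6%, 28.3% and 29.7% in rrp6Δtri1Δ, without overlap, and 26.1% and 22.1% in dcr1Δtri1Δ. Their mean lengths overlapped, at 22.7 and 22.2 nt in rrp6Δ and 23.5, 22.6 and 22.4 nt in rrp6Δtri1Δ. In dcr1Δtri1Δ they were 22.8 and 21.7 nt, against 21.1 to 22.5 nt for the steps of dcr1Δ. Among the 4 step sizes of dcr1Δ it was 49.6%, 54.0%, 35.8% and 19.0%, so the mean for that genotype rested on components that differed.

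**Figure D2:**
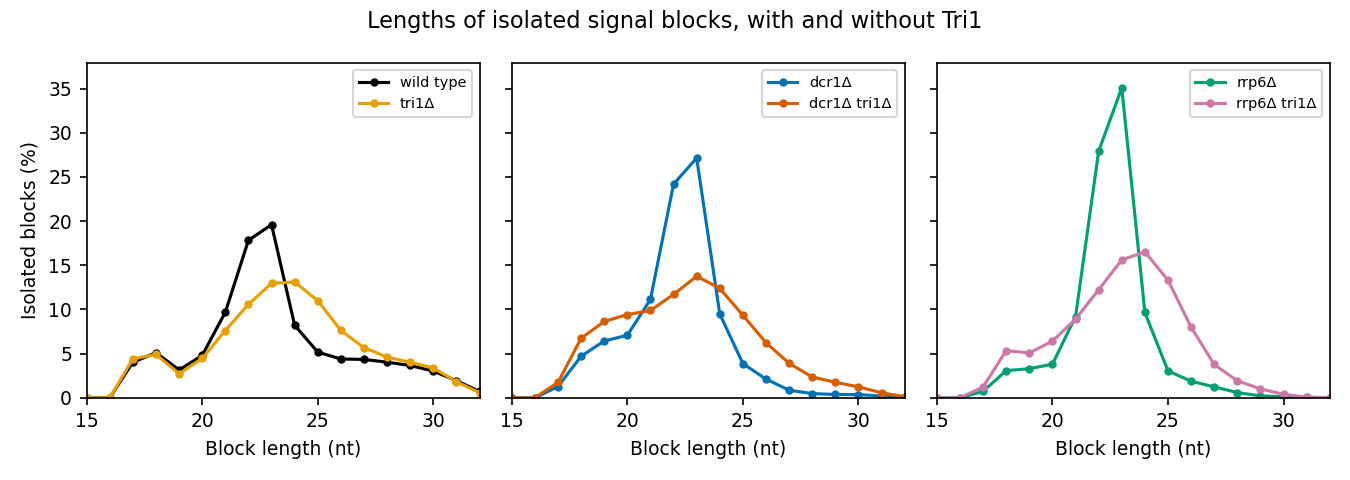
Length of isolated signal blocks (nt, horizontal axis) against their share of all isolated blocks (percent, vertical axis), with Tri1 present and absent in 3 backgrounds; each line is 1 genotype. The peak at 22 and 23 nt was lower without Tri1 in each panel, 37.4% against 23.6%, 51.3% against 25.5% and 63.0% against 27.9% of blocks.

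**Figure D3:**
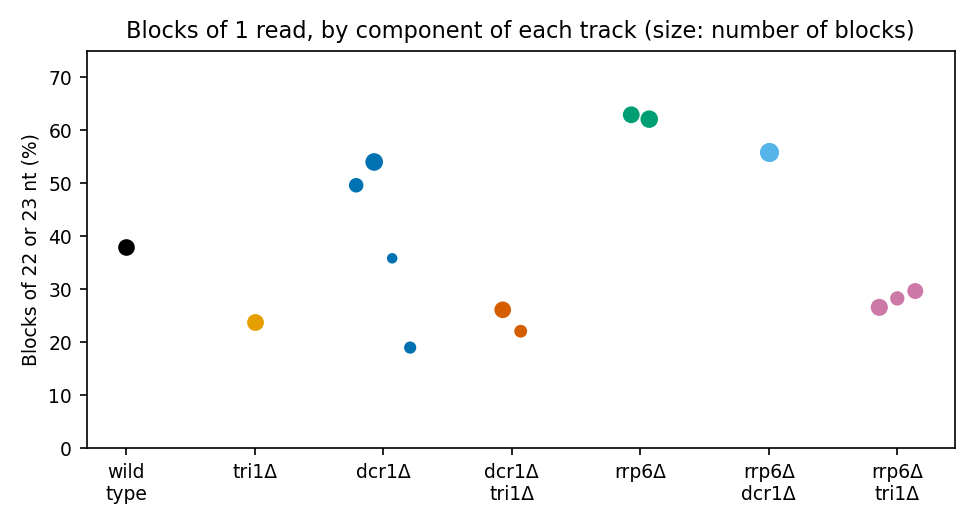
Share of blocks of 1 read that were 22 or 23 nt long (percent, vertical axis) for each component of a genotype's track, as 1 point per step size, with point size rising with the number of blocks. The 2 rrp6Δ points sit at 62.1% and 62.9% and the 3 rrp6Δtri1Δ points between 26.6% and 29.7%, while the 4 dcr1Δ points spread from 19.0% to 54.0%.

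A single species in the rDNA, TCTTGTTGGTAGGCAAAAAATTA, had a fixed 5′ end 55 bases past the end of the 28S rRNA genes; 1 copy starts at 16872 on the minus strand of chromosome III, beside the gene at 16927 to 20411. It was singled out after its values were seen. The share that reached past base 23 was taken as the signal at base 24 in percent of the plateau. Without Tri1 it was larger: 41.9% in tri1Δ against 3.96% in wild type, 44.1% in dcr1Δtri1Δ against 1.58% in dcr1Δ, and 54.0% in rrp6Δtri1Δ against 2.79% in rrp6Δ. In rrp6Δdcr1Δ this share was 1.47%. At the SPBC530.02 site the signal at base 24, relative to that near the 5′ end, was 16.8% in wild type and 70.6% in tri1Δ. It was 8.53% in dcr1Δ and 46.8% in dcr1Δtri1Δ, and 19.9% in rrp6Δ and 86.8% in rrp6Δtri1Δ.

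**Figure D4:**
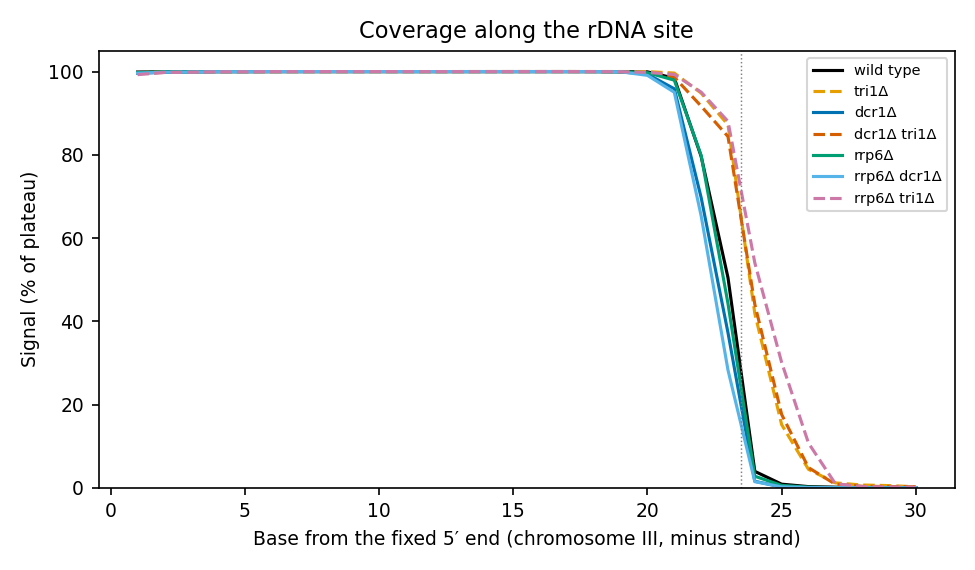
Signal along the rDNA species, from its fixed 5′ end on the minus strand of chromosome III (base number, horizontal axis), as a percent of its plateau (vertical axis); each line is 1 genotype, dashed where tri1 was deleted, and the dotted line marks the end of base 23. At base 24, the first past it, signal stood at 41.9%, 44.1% and 54.0% of the plateau in the 3 genotypes without Tri1 and at 1.47% to 3.96% in the other 4.

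A 5′ U was common in every genotype. In centromeres 91.2% (83.9 to 95.9) of 102 isolated blocks began with U in wild type, 83.2% (75.2 to 89.4) in tri1Δ, 88.1% in dcr1Δ, 84.0% in dcr1Δtri1Δ, 92.2% in rrp6Δ, 79.7% in rrp6Δdcr1Δ and 85.8% in rrp6Δtri1Δ. On the sense strand of protein-coding genes it was 44.5% in wild type and 46.4% in tri1Δ, 65.5% and 62.9% in dcr1Δ and dcr1Δtri1Δ, and 86.2%, 80.5% and 74.97% in rrp6Δ, rrp6Δdcr1Δ and rrp6Δtri1Δ. Because centromeric signal is dense, isolated blocks there were few.

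The strands of genes differed less in strains without Rrp6. Among genes overlapping no other gene, the median ratio of sense to antisense signal was 3.12 in wild type, 3.29 in tri1Δ, 4.80 in dcr1Δ and 3.42 in dcr1Δtri1Δ, but 1.23 in rrp6Δ, 1.40 in rrp6Δdcr1Δ and 1.40 in rrp6Δtri1Δ. The plus strand held 44.1% of centromeric signal outside tRNA genes in wild type, 50.4% in tri1Δ, 47.2% in rrp6Δ and 50.2% in rrp6Δtri1Δ, against 35.2% in dcr1Δ, 33.0% in dcr1Δtri1Δ and 44.8% in rrp6Δdcr1Δ. The 2 low values came mainly from chromosome II, with 14.3% in both genotypes, while chromosomes I and III had 40.6% to 47.9%. Genes with signal on both strands numbered 255 to 445 of 458.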

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

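The tests of the rDNA species and of the likeness of sites to it or to the adaptor, and the blocks of 1 read with 50 empty positions, were chosen after the result was seen.

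The effect of a deletion had opposite signs in 2 backgrounds for 3 region classes by a rule, and none of these differences was tested. The rule asked for a log2 ratio of at least 0.2 on both scalings. Where both genotypes had been split, it also asked for recovered libraries without overlap. Because dcr1Δ was not split, this was not asked of dcr1Δtri1Δ against dcr1Δ or of dcr1Δ against wild type. Each of the 3 classes has 1 of these comparisons on 1 side. For tri1Δ against wild type it set 1 library against 1. Other classes also differed in sign on the main scaling alone, such as protein-coding antisense (0.43 in tri1Δ against wild type, -1.22 in dcr1Δtri1Δ against dcr1Δ). The rRNA, mating-type and intergenic classes were left out of the rule. Protein-coding sense signal was higher by 0.24 in tri1Δ than in wild type (log2) but differed by -1.49 between dcr1Δtri1Δ and dcr1Δ. For snRNA and snoRNA genes the same comparisons gave 0.21 and -1.66. Outside the rDNA arrays the values between dcr1Δtri1Δ and dcr1Δ were only -0.42 and -0.60. The sense value includes the fall at the single site of SPBC530.02, which held a large part of the sense signal of dcr1Δ. The sense value outside the arrays may therefore rest on that site, and its sign without the site was not computed. Tf2 elements differed by 2.64 between dcr1Δ and wild type and by -3.17 between rrp6Δdcr1Δ and rrp6Δ (6.44 and -2.15 outside the arrays).

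Fewer blocks were 22 or 23 nt long in the 3 genotypes without Tri1, and more were 24 to 27 nt. Merging of neighbouring reads is argued against, since blocks of 1 read with 50 empty positions around them kept at least 97.8% of the fall at 22 and 23 nt. At the rDNA species, with its fixed 5′ end, the percent of plateau left at base 24 was higher by at least 37.9 points in each pair. Trimming of 3′ ends by Tri1 may explain this. Of fixed 5′ ends elsewhere, ties left out, 96.6% went the same way: 19 of 20 for dcr1Δtri1Δ against dcr1Δ (2 of 11 for rrp6Δdcr1Δ against dcr1Δ, with Tri1 in both), 8 of 8 for tri1Δ, in centromeres or tRNA genes with a median of 91.3% past base 23 in wild type already, and 1 of 1 for rrp6Δtri1Δ (2 of 2 for rrp6Δ against wild type), so 2 of the 3 pairs decide nothing. Sites outside the arrays that resemble the rDNA species were not left out. The dcr1Δtri1Δ pair may therefore partly repeat the result at that species. The test set beforehand for trimming compared blocks sharing a 5′ end with those sharing a 3′ end. The percent longer without Tri1 was higher among the former by 0.717 to 9.31 points. For dcr1Δtri1Δ against dcr1Δ and rrp6Δtri1Δ against rrp6Δ the interval of this difference held both signs. By the bound set beforehand this test went against trimming. Pairs with Tri1 in both tracks differed by 9.24 and -3.07, so that bound cannot decide. Trimming thus rests mainly on the rDNA species, a test chosen after the result was seen. A different size selection in library preparation stays open. Only 1 site with a fixed 3′ end could be compared, and the rise without a 5′ U was 0.258 to 0.982 of that with it.

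Some genes had nearly all signal at 1 site. Of those higher in dcr1Δtri1Δ than in dcr1Δ, 75% resembled the rDNA species against 0.064% of random positions beginning with T, so reads of that species aligned with mismatches are a candidate explanation. Among those higher in dcr1Δ than in wild type 11.5% did, which leaves most of them, SPBC530.02 and mfs2 included, without a tested technical explanation. Of those lower in dcr1Δ than in wild type 50% held a run of 5′ adaptor bases, against 0.244% of random positions, so reads carrying adaptor may be their source. No biological explanation was tested for these genes.

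The ura4 signal of strains with Dicer was high for a gene of the chromosome arm. Reads of a repeat are argued against, because 0% of the 22-base windows of ura4 occur elsewhere in the reference. Antisense signal was 21.9% of sense in wild type, and both were low without Dicer, so a ura4 copy placed in heterochromatin may give rise to Dicer products; the labels used here name no such copy, and its place was not tested.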

How the results depend on the processing

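Chosen after the data were examined were the base outside the rDNA arrays, the counts without centring on the median gene and without resembling genes, blocks of 1 read with 50 empty positions, and limma on recovered libraries with each left out. Higher and lower genes are those at least 1 (log2) from the median gene. No paired analysis was possible because the tracks of replicated genotypes hold all libraries together and the recovered libraries carry no replicate number. Leaving out each library on the deposited tracks, and a replicate block, were not run for the same reason, and the test of dg and dh repeats alone was not run because the annotation has 0 such features.

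Of 1200 alternative values for named genes 1199 moved, with the sign given in the report, and 1 reversed; pex7 in rrp6Δdcr1Δ against rrp6Δ, at 2.84, went down to 0.29, and rpl1902 in rrp6Δ against wild type, at -4.07, ranged from -6.09 to -1.26. Counts of higher genes stayed within 1.5 times the reported count in 43 of 72 alternatives and counts of lower genes in 46 of 72. The centromere ratio reversed in 6 of 42 alternatives and moved in 30, the median gene reversed in 10 of 54 and moved in 43, and the subtelomere ratio moved in 11 of 12 and reversed in 0. For dcr1Δ against wild type it was -8.86 with the outer 20 kb and -5.35 with the outer 100 kb, against -7.89. Sense to antisense ratios moved in 8 of 14 alternatives and reversed in 0. The share at 22 and 23 nt moved beyond its counting interval in 15 of 28 and the centromeric 5′ U share in 7 of 28. With leave-one-out, limma gave 4 to 58 genes against 15. It gave 4 (0 up) when the first and 4 (1 up) when the second rrp6Δ library was left out, where the lone library was assumed to vary like the others, and 13, 58 and 37 without the first, the second and the third rrp6Δtri1Δ library. Without centring it gave 8 up and 3 down. In rrp6Δdcr1Δ 1 ppm stood for 2.71 placed reads, and the 2 dcr1Δtri1Δ libraries held 11.2 M and 1.57 M read bases outside the rDNA arrays.

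The values that reversed, and those that moved among the counts of genes, the centromere ratios and the block shares, follow; the cause was not tested. With signal outside rRNA, tRNA, snRNA and snoRNA genes as the base, the centromere log2 ratio was -0.00967 in tri1Δ against wild type, -8.00 in dcr1Δ against wild type, -0.69 in dcr1Δtri1Δ against dcr1Δ, -0.42 in rrp6Δ against wild type and 0.15 in rrp6Δtri1Δ against rrp6Δ. On the deposited scale, the centromere log2 ratio was -0.97 in tri1Δ against wild type, -11.69 in dcr1Δ against wild type, -2.87 in dcr1Δtri1Δ against dcr1Δ, -0.46 in rrp6Δ against wild type, -5.56 in rrp6Δdcr1Δ against rrp6Δ and -0.64 in rrp6Δtri1Δ against rrp6Δ (reversed). Higher genes were 0 in tri1Δ against wild type, 14 in dcr1Δ against wild type and 13 in dcr1Δtri1Δ against dcr1Δ. Lower genes were 183 in dcr1Δ against wild type and 203 in dcr1Δtri1Δ against dcr1Δ. Median-gene ratios were -0.27 in tri1Δ against wild type (reversed), -0.42 in dcr1Δ against wild type (reversed), -0.80 in rrp6Δdcr1Δ against rrp6Δ (reversed) and -0.60 in rrp6Δtri1Δ against rrp6Δ (reversed). With a size factor over protein-coding genes, the centromere log2 ratio was -0.17 in tri1Δ against wild type, -10.02 in dcr1Δ against wild type, 0.31 in dcr1Δtri1Δ against dcr1Δ (reversed), -5.51 in rrp6Δ against wild type, -4.75 in rrp6Δdcr1Δ against rrp6Δ and 0.0217 in rrp6Δtri1Δ against rrp6Δ. Higher genes were 1 in tri1Δ against wild type, 68 in dcr1Δ against wild type, 82 in dcr1Δtri1Δ against dcr1Δ and 220 in rrp6Δ against wild type. With a pseudocount of 0.1, higher genes numbered 68 in tri1Δ against wild type, 367 in dcr1Δ against wild type and 194 in dcr1Δtri1Δ against dcr1Δ. Lower genes were 95 in tri1Δ against wild type, 323 in dcr1Δ against wild type, 171 in dcr1Δtri1Δ against dcr1Δ and 671 in rrp6Δ against wild type. With a pseudocount of 10, higher genes numbered 0 in tri1Δ against wild type, 39 in dcr1Δ against wild type, 8 in dcr1Δtri1Δ against dcr1Δ, 137 in rrp6Δdcr1Δ against rrp6Δ and 29 in rrp6Δtri1Δ against rrp6Δ. Lower genes were 1 in tri1Δ against wild type, 7 in dcr1Δ against wild type, 21 in dcr1Δtri1Δ against dcr1Δ, 66 in rrp6Δ against wild type, 171 in rrp6Δdcr1Δ against rrp6Δ and 26 in rrp6Δtri1Δ against rrp6Δ. With capped heights, the centromere log2 ratio was -0.00632 in tri1Δ against wild type, -5.15 in dcr1Δ against wild type, 0.77 in dcr1Δtri1Δ against dcr1Δ (reversed), -0.47 in rrp6Δ against wild type, -2.16 in rrp6Δdcr1Δ against rrp6Δ and -0.0486 in rrp6Δtri1Δ against rrp6Δ (reversed). Higher genes were 229 in dcr1Δtri1Δ against dcr1Δ. Lower genes were 179 in dcr1Δtri1Δ against dcr1Δ. Median-gene ratios were 0.16 in dcr1Δtri1Δ against dcr1Δ (reversed) and -0.0893 in rrp6Δtri1Δ against rrp6Δ (reversed). The gene SPBC530.02 was at -1.44 in dcr1Δ against wild type (reversed). With signal outside the rDNA arrays as the base, the centromere log2 ratio was -0.00742 in tri1Δ against wild type, -4.26 in dcr1Δ against wild type, 0.42 in dcr1Δtri1Δ against dcr1Δ (reversed), -0.40 in rrp6Δ against wild type, -2.17 in rrp6Δdcr1Δ against rrp6Δ and -0.0426 in rrp6Δtri1Δ against rrp6Δ (reversed). Higher genes were 233 in dcr1Δtri1Δ against dcr1Δ. Lower genes were 183 in dcr1Δtri1Δ against dcr1Δ. Median-gene ratios were 0.17 in dcr1Δtri1Δ against dcr1Δ (reversed) and -0.0617 in rrp6Δtri1Δ against rrp6Δ (reversed). With tRNA genes and 200 bp around them left out of the centromere, the centromere log2 ratio was -0.00774 in tri1Δ against wild type, -9.88 in dcr1Δ against wild type, -0.78 in dcr1Δtri1Δ against dcr1Δ, -0.45 in rrp6Δ against wild type, -3.23 in rrp6Δdcr1Δ against rrp6Δ and 0.0976 in rrp6Δtri1Δ against rrp6Δ. Without a filter, higher genes numbered 401 in dcr1Δ against wild type, 1494 in rrp6Δ against wild type and 538 in rrp6Δdcr1Δ against rrp6Δ. Lower genes were 21 in dcr1Δ against wild type, 145 in dcr1Δtri1Δ against dcr1Δ, 1174 in rrp6Δ against wild type and 622 in rrp6Δdcr1Δ against rrp6Δ. With a stricter filter, higher genes numbered 113 in dcr1Δ against wild type, 269 in rrp6Δ against wild type, 148 in rrp6Δdcr1Δ against rrp6Δ and 49 in rrp6Δtri1Δ against rrp6Δ. Lower genes were 82 in dcr1Δ against wild type, 159 in rrp6Δ against wild type and 177 in rrp6Δdcr1Δ against rrp6Δ. Median-gene ratios were -0.0136 in rrp6Δtri1Δ against rrp6Δ (reversed). In the combined track, the centromere log2 ratio was 0.23 in rrp6Δtri1Δ against rrp6Δ. Higher genes were 46 in rrp6Δtri1Δ against rrp6Δ. Lower genes were 98 in dcr1Δ against wild type. Median-gene ratios were -0.22 in rrp6Δtri1Δ against rrp6Δ (reversed). Without centring on the median gene, higher genes numbered 1249 in dcr1Δ against wild type, 19 in dcr1Δtri1Δ against dcr1Δ, 2327 in rrp6Δ against wild type and 1838 in rrp6Δdcr1Δ against rrp6Δ. Lower genes were 12 in dcr1Δ against wild type, 436 in dcr1Δtri1Δ against dcr1Δ, 3 in rrp6Δ against wild type and 72 in rrp6Δdcr1Δ against rrp6Δ. For blocks with 50 empty positions on each side, the percent at 22 and 23 nt was 38.2 in wild type, 60.6 in rrp6Δ, 56.7 in rrp6Δdcr1Δ and 25.8 in rrp6Δtri1Δ. Centromeric 5′ U was 84.6 in dcr1Δ, 87.1 in rrp6Δ and 80.4 in rrp6Δtri1Δ. For blocks weighted by height, the percent at 22 and 23 nt was 36.1 in wild type, 22.7 in tri1Δ, 40.7 in dcr1Δ, 23.9 in dcr1Δtri1Δ and 58.6 in rrp6Δdcr1Δ. Centromeric 5′ U was 86.5 in dcr1Δtri1Δ. For blocks of 1 read with 50 empty positions, the percent at 22 and 23 nt was 38.7 in wild type, 60.4 in rrp6Δ, 55.7 in rrp6Δdcr1Δ and 26.1 in rrp6Δtri1Δ. Centromeric 5′ U was 84.5 in dcr1Δ, 76.0 in rrp6Δdcr1Δ and 79.8 in rrp6Δtri1Δ. For blocks of 1 read, the percent at 22 and 23 nt was 62.5 in rrp6Δ and 55.95 in rrp6Δdcr1Δ.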

Other observations

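The count of neighbouring genes was chosen after the result was seen, as were the counts of step sizes.

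Of the 15 genes past the limma threshold between rrp6Δtri1Δ and rrp6Δ, 12 had another gene changed the same way within 20 kb, 7 of 7 that rose and 5 of 8 that fell; with the first or the second rrp6Δ library left out only 0 or 1 genes rose. In 10000 random draws of as many tested genes the mean was 0.357 and the highest 6. The genes gas2, tri1 and dbl8 lie around the deleted tri1, and ptl1, ste6, glm2 and mme1 lie beside rmr1. The group that fell, from SPBC18E5.10 to rpt6, ends at 2122816 on chromosome II, and the silent mating-type interval starts at 2132586.

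The dcr1Δ tracks held 4 step sizes where the labels give 3 libraries. The fourth had 3946 blocks of 1 read, of which 19.0% were 22 or 23 nt long and 43.3% began with U, against 54.0% and 75.7% for the second, which had 55544 blocks. The combined track of rrp6Δtri1Δ held 2 of the 3 step sizes of its strand tracks.

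Of the 10 genes highest in rrp6Δ against wild type 3 lay within 50 kb of a centromere interval. Among the genes tested by limma between rrp6Δtri1Δ and rrp6Δ the share was 3.73%. It was not computed for the genes of rrp6Δ against wild type. The count of 3 was the highest of 12 such sets, of which 10 had 0 and the 10 lowest of rrp6Δtri1Δ against rrp6Δ had 2. Of the 3 genes, prm1 and lys1 overlap.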
